A study of Mus musculus with 8 samples.

How the data were processed

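Genomic DNA from the hippocampus of C57BL/6 mice was profiled for 5-hydroxymethylcytosine (5hmC), an oxidised form of 5-methylcytosine that is abundant in neurons. Per the labels' protocols, the DNA was sonicated, an azide-bearing glucose was attached to each 5hmC by a phage glucosyltransferase, biotin was added by click chemistry, and the biotin-carrying fragments were captured on streptavidin beads, amplified and sequenced. The assay therefore measures local enrichment of 5hmC-containing fragments and gives neither a level per cytosine nor the strand. Enrichment also depends on the density of cytosines that can carry the mark and on PCR amplification, which the deposited files do not allow to be separated.

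The deposited files are 8 peak lists, one per sample, with a chromosome, a start, an end, a peak name and a score for each peak. The submitters' processing notes name CASAVA 1.4, Bowtie 0.12.9, MACS 1.4.2 and the mouse build mm9. Peaks had been called in each sample alone, as the separate lists and their own peak numbering show. The score is the authors' value for each peak as deposited. The caller MACS writes it as −10 times the log10 of the peak p-value, and the lowest score was 50.0 in 7 lists and 50.3 in the list of aged enriched replicate 2. Scores were used only to describe, rank or filter peaks within 1 list. The peak coordinates as deposited were taken as mm9 and are printed counted from 1. Caller settings, the background library given to the caller, read filters and the number of reads per sample are not given in the sources used here. The depth of each sample is therefore unknown, and a longer or stronger list can reflect more reads or a better capture as well as more 5hmC. No interval that needs read counts was computed.

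Samples were grouped by the age and housing in their labels into 4 groups of 2. The numbers 1 and 2 in the labels were not used to pair samples. The labels do not say whether the 2 samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The main tests, the alternatives and the rule for the regions and windows named were fixed before the data were examined, except for the alternatives described in the closing part as chosen later. That plan did not include the permutation test of the interaction of age and housing or the background of shifted lists for the overlap. It also did not include naming the regions with a peak in all 8 samples.

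Peak number, length of genome under peaks and median peak width per sample were compared on the log2 scale by exact two-sided permutation tests of 4 samples against 4 (70 assignments, smallest possible p 0.0286). Ratios between groups in these measures come from the log2 values. They are ratios of geometric means and can differ from the ratio of the arithmetic means printed beside them. The interaction of age and housing was tested by permuting housing within each age (36 assignments, smallest possible p 0.0556). A comparison of 2 samples with 2 has 3 splits, so its exact permutation test cannot go below p = 0.333, and those values are given without a test. The Jaccard index of a pair of samples was the length under peaks in both lists as a percent of the length under peaks in either, counting overlaps of at least 1 bp. Its background was the same index after shifting 1 list along its chromosomes by 2 to 20 Mb, with 10 random shifts. Peaks of all samples that overlapped by at least 1 bp were merged into regions. A region was present in a sample with at least 1 bp under a peak of that sample. Regions with a peak in both samples of 1 group and neither sample of the other were counted beside the same counts under the other 2 splits of those 4 samples. Regions with a peak in 4 samples and in none of the other 4 were counted for age, for housing and for each of the 35 splits into 4 and 4.

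For tests along the genome, peaks were counted by midpoint in windows of 1 Mb. Of 2207 windows with a peak, the 1548 with a mean of at least 5 peaks per sample were tested. Counts with a pseudocount of 1 peak were divided by the number of peaks in the sample's list, expressed per 1000000 peaks and taken as log2 values. A fold change is therefore relative to the length of the list. The pseudocount shrinks changes in windows with few peaks. It also adds more per 1000000 peaks to a shorter list, which can raise such windows in the aged enriched samples. limma with an intensity trend was fitted to all 8 samples as 4 groups sharing 1 estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. Array weights, which are lower where the samples of a group vary more, were estimated later. They were 1.24 in young control, 1.82 in young enriched, 0.91 in aged control and 0.49 in aged enriched samples. The shared spread can therefore be too wide for young and too narrow for aged samples. The percent of peaks on each chromosome was tested by the same limma model on the log2 scale, but without the intensity trend and without a minimum of peaks. The window fit was tested on simulated counts with 200 windows changed at random, in 10 runs and on 1540 windows. Every simulated sample had the same dispersion of 1e-04, the lowest allowed, which is close to counting error alone. In the aged housing contrast it found 19.1% of windows changed 1.5-fold, 55.7% of those changed 2-fold and 83.3% of those changed 3-fold, and 9.86% of its calls were false. In the young housing contrast the shares were 14.7%, 60.1% and 86.5%, with 0.85% of calls false. The unequal spread of the real groups was not simulated, so these shares may not hold for the data. The aged contrast includes the 2 shortest lists, and the pseudocount was the same for every list.

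For each set of regions, the rule named the 5 with the highest mean percentile of their peaks' scores within their own lists, in the samples that had them. For each window contrast it named the 3 windows with the smallest p in each direction. Alternatives were a score of at least 100, equally long lists of the 25548 top-scoring peaks, autosomes only, regions merged over gaps of 500 bp, 50% of a region covered, a 50% reciprocal overlap, windows of 250 kb, base pairs in place of peaks, pseudocounts of 0.25 and 4 peaks, no minimum, quantile normalization, permutation within the other factor, a replicate block and leaving out each sample. The gene table at hand is of the build GRCm38, while all 8 lists hold peaks past the end of chromosome 1 in that build. The planned tests per gene, of gene lists and of gene features were therefore not run, and no position is given a gene name. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.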

Results

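5hmC was mapped in the hippocampus, a brain region needed for forming memories, of young (6 weeks) and aged (18 months) mice kept in standard cages or given an enriched environment. Enrichment meant 5 h per day over 4 weeks in a larger chamber with toys, tunnels and a running wheel. The design asks whether such housing alters the genomic distribution of 5hmC and whether its effect depends on age. Each of the 4 groups (young control, young enriched, aged control and aged enriched) had 2 samples, and the 8 lists held 393283 peaks. The number of reads per sample is unknown, so the length of each list is the only measure of how much was detected.

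Aged enriched samples had the shortest lists and the smallest length of genome under 5hmC peaks. Lists held 61344.5 ± 24940 peaks in young control, 58477 ± 1393 in young enriched, 48630 ± 15033 in aged control and 28190 ± 3736 in aged enriched samples (mean ± SD, n = 2 each). Peaks covered 65.8 ± 29.3 Mb, 58.4 ± 4.16 Mb, 44.9 ± 19.2 Mb and 16.0 ± 3.25 Mb in the same order (SD, n = 2 each). Replicates of the young control group differed more than most groups did, with 43709 and 78980 peaks. Aged enriched replicate 2 stood apart in the shape of its peaks, with a median width of 430 bp against 650 to 952 bp in the other samples. In its list 72.4% of peaks had a score of 100 or more, against 9.92% to 31.9% in the other lists.

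**Figure D1:**
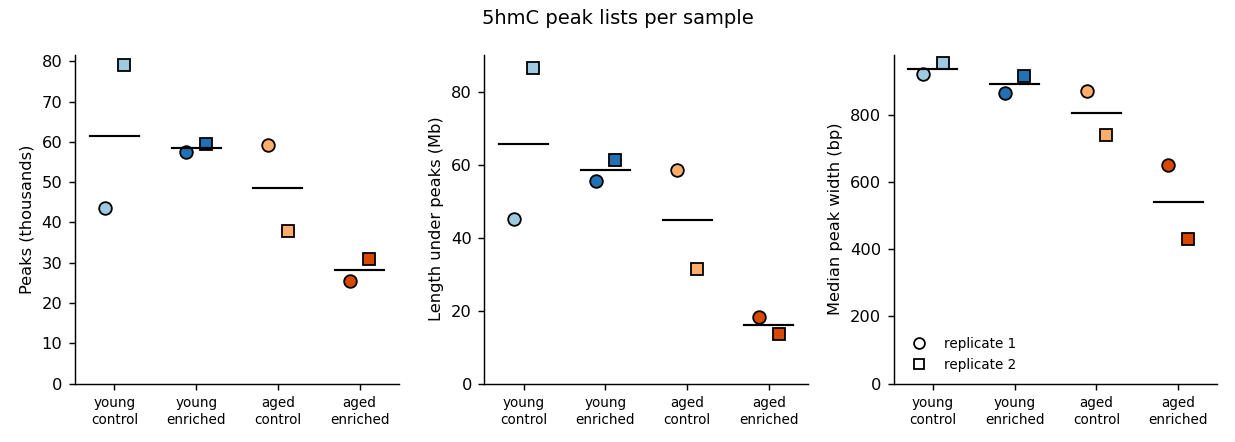
Number of peaks (axis in units of 1000), length of genome under peaks (Mb) and median peak width (bp) in each of the 8 samples, by group; circles are replicate 1, squares replicate 2 and lines the mean of the 2. Both aged enriched samples, with 25548 and 30832 peaks, lie below the 6 other samples in all 3 panels.

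By geometric mean, aged samples had 0.623 times as many peaks as young samples, a difference that did not pass the exact permutation test (p = 0.0857). The arithmetic means were 38410 ± 14807 in aged and 59911 ± 14516 in young samples (SD, n = 4 each). The length under peaks was 0.431 times that in young samples (exact permutation p = 0.0857), and the median width was 0.713 times (exact permutation p = 0.0571). Without aged control replicate 1 the log2 difference in length went from −1.21 to −1.60 and that in width from −0.49 to −0.63, and both passed the exact permutation test. Without aged enriched replicate 2 they went to −0.90 and −0.29, and neither passed. By geometric mean, enriched samples had 0.767 times as many peaks as control samples, with exact permutation p = 0.371. The arithmetic means were 43334 ± 17637 in enriched and 54987 ± 18346 in control samples (SD, n = 4 each). The length under peaks was 0.587 times that of control samples (exact permutation p = 0.286) and the median width 0.792 times (exact permutation p = 0.20). Without aged enriched replicate 2 the log2 difference in width with housing went from −0.34 to −0.11. Within ages, the ratio of enriched to control was 0.995 for peak number and 0.935 for length in young samples. In aged samples it was 0.591 and 0.369, with both aged enriched lists below both aged control lists. With a score of at least 100 the log2 difference in aged peak number went from −0.76 to −0.40, and aged enriched replicate 2 (22310 peaks) lay above both aged control samples (14787 and 6625). In equally long lists the log2 difference in aged length went from −1.44 to −0.91. The exact permutation test of this difference between ages gave p = 0.333 for peak number and 0.222 for length. Age had ratios of 0.808 for peak number in control and 0.48 in enriched housing. The first turned direction without young control replicate 2 (log2 0.12 against −0.31 with all samples) and without aged control replicate 2 (0.012). The ratio of enriched to control in young samples turned without young control replicate 2 (log2 0.42 for peak number and 0.37 for length), and that for peak number also without young enriched replicate 1 (0.017).

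Peaks were spread over all autosomes and nearly missing from the X chromosome. The mean density over samples was highest on chromosomes 11 (27.96 ± 9.91 peaks per Mb, SD, n = 8) and 17 (27.0 ± 9.56) and lowest among autosomes on chromosome 3 (13.9 ± 5.19), counted up to the last peak on each. The X chromosome carried 7 to 25 peaks per sample, 129 in all. Its density was 0.232% to 0.816% of the autosomal density, which is 123-fold to 432-fold lower. The percent of a list's peaks that lay on X ran from 0.0157% (95% exact Clopper-Pearson interval 0.00716% to 0.0297%) in young enriched replicate 1 to 0.0551% (0.0321% to 0.0883%) in aged enriched replicate 2. These intervals cover counting error only. None of the 84 merged regions on X had a peak in all 8 samples.

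**Figure D2:**
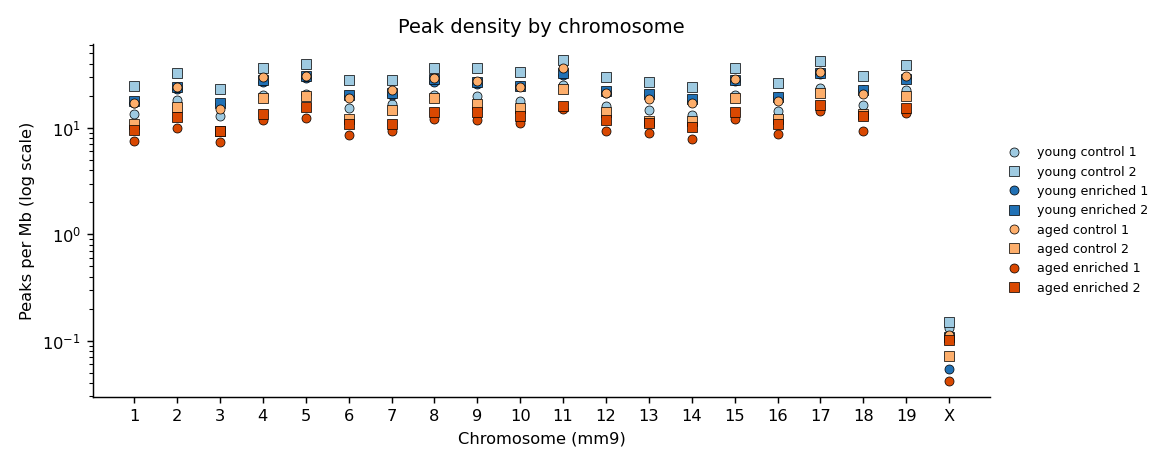
Peaks per Mb (log scale) on each mm9 chromosome in each of the 8 samples, coloured by group, with circles for replicate 1 and squares for replicate 2. Autosomes hold 7.35 to 43.4 peaks per Mb in every sample, and X holds 0.0421 to 0.15.

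Peak positions were shared between samples far above chance. The Jaccard index of 28 pairs of samples ran from 5.79% to 35.3%, which was 12.7-fold to 23.5-fold above randomly shifted lists. It averaged 30.8% between young samples, 10.6% between aged samples and 7.25% in pairs with aged enriched replicate 2. The index can fall where the lengths under peaks are short or unequal. Relative to shifted lists these pairs ran from 19.75-fold to 23.47-fold, 12.67-fold to 19.25-fold and 12.65-fold to 15.89-fold. Pairs from the same group averaged 21.5% and pairs from different groups 17.7%, a difference of 3.87 points that passed a one-sided exact permutation test over assignments of samples to pairs (p = 0.0381). With a score of at least 100 the difference was 3.43 points (exact permutation p = 0.0667), and leaving out any 1 young sample or any 1 aged control sample also ended the call, with differences of 1.66 to 5.31 points. Pairs from the same group always share an age, while 16 of the 24 other pairs join a young and an aged sample, so this difference is not one of group alone. Within ages, pairs from the same group averaged 30.1% and pairs from different housing 31.2% in young samples, and 12.9% and 9.39% in aged samples. The aged enriched pair (5.79%) was the lowest of all 28, but it has the 2 smallest lengths under peaks. Relative to shifted lists it was 15.49-fold, which was not the lowest. With assignments kept within each age the difference was 1.24 points (one-sided exact permutation p = 0.333).

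**Figure D3:**
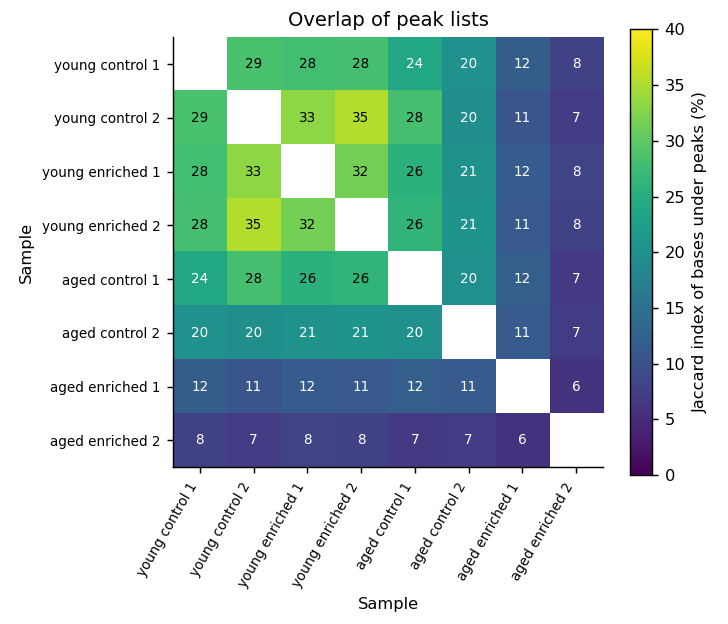
Jaccard index (%) of the bases under peaks for each pair of the 8 samples; darker cells share less. Pairs of young samples lie between 27.9% and 35.3% and pairs with aged enriched replicate 2 between 5.79% and 8.18%.

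Merging the lists gave 156744 regions with a median width of 892 bp. A peak was found in only 1 sample in 73260 regions (46.7%, median width 695 bp) and in all 8 samples in 2058 regions (1.31%, median width 2733 bp). The strongest shared regions lay on chromosome 8 at 73436139 to 73441659, on chromosome 5 at 143548220 to 143550886, on chromosome 10 at 79195366 to 79204079 and 80605855 to 80608714, and on chromosome 7 at 4980175 to 4984005 (mm9). At the first of these, scores ran from 316 in aged enriched replicate 2 to 1051 in young control replicate 2. Chromosome 17 had the highest percent of its regions in all 8 samples (1.85%), and chromosome 6 the lowest among autosomes (0.831%).

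In young mice, no difference in 5hmC peaks between enriched and control housing was detected beyond that between replicates. Both enriched and neither control sample had a peak in 3343 regions, led by chromosome 6 at 53567852 to 53569641, chromosome 18 at 75540589 to 75542631 and chromosome 17 at 43216001 to 43218777. The reverse held for 4359 regions, led by chromosome 1 at 168328548 to 168330648, chromosome 6 at 48985641 to 48988089 and chromosome 1 at 135152358 to 135153873. The direction turned without young enriched replicate 1 (16458 and 8214) or replicate 2 (15984 and 8751), when a peak in the 1 remaining enriched sample was enough to count. The total of 7702 was below the 10155 and 9131 regions that the other splits of the same 4 samples gave. The leading chromosome 1 region had scores of 233 and 277 in the young control lists, and 60.1 in aged control replicate 1.

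By limma, 0 of 1548 windows of 1 Mb differed between young enriched and young control samples, with 15 at an unadjusted p under 0.05 where chance gives 77.4. A limma fit of the 4 young samples alone also called 0, with 61 at an unadjusted p under 0.05. The 15 lay below chance, and array weights were higher in young than in aged samples. The shared spread may therefore be too wide here, so the main fit may miss changes in young samples. Even in simulated counts it found only 14.7% of windows changed 1.5-fold. The smallest p among higher windows was at 68 to 69 Mb of chromosome 17 (log2 difference 0.78 ± 0.31 SE, limma adjusted p = 0.996). Next came 152 to 153 Mb of chromosome 4 (0.57 ± 0.25 SE) and 77 to 78 Mb of chromosome 18 (0.54 ± 0.24 SE), the last of which had −0.030 in equally long lists. Among lower windows these were 4 to 5 Mb of chromosome 5 (−0.99 ± 0.37 SE), 68 to 69 Mb of chromosome 9 (−0.61 ± 0.25 SE) and 54 to 55 Mb of chromosome 1 (−0.81 ± 0.36 SE). No chromosome changed its share of peaks in young mice by limma, with the smallest adjusted p at 0.665.

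In aged mice, more regions had a peak in both control and no enriched samples than the reverse. Both aged control and neither aged enriched sample had a peak in 8778 regions, 9.97 times the 880 regions with the reverse. The leading region of the larger set, on chromosome 18 at 65782866 to 65785412, had a peak in all 6 samples outside the aged enriched group, with scores of 307 to 578. Chromosome 8 at 28230680 to 28233044 (scores 252 to 376), chromosome 15 at 79747122 to 79750064 (125 to 333) and chromosome 8 at 124783626 to 124790971 (109 to 463) had the same pattern. Chromosome 7 at 112764994 to 112768151 had a peak in 5 samples, without young enriched replicate 1.

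The smaller set, with peaks in both aged enriched samples, was led by chromosome 4 at 150622538 to 150624005, chromosome 9 at 42549603 to 42550839 and chromosome 1 at 13158024 to 13158952, each with a peak in 3 young samples too. The fourth, on chromosome 2 at 134637861 to 134638570, had a peak in the aged enriched samples only (scores 95.5 and 275). The total of 9658 regions exceeded the 5941 and 5422 of the other splits of the same samples, a difference that was not tested. The aged enriched lists were also the shortest, and equally long lists gave 3860 regions with control peaks only and 1301 with enriched peaks only. The direction turned without aged enriched replicate 1 (12536 control only, 16851 enriched only) and the sets came close without aged enriched replicate 2 (11677 and 10590), where a peak in the 1 remaining enriched sample was enough to count.

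**Figure D4:**
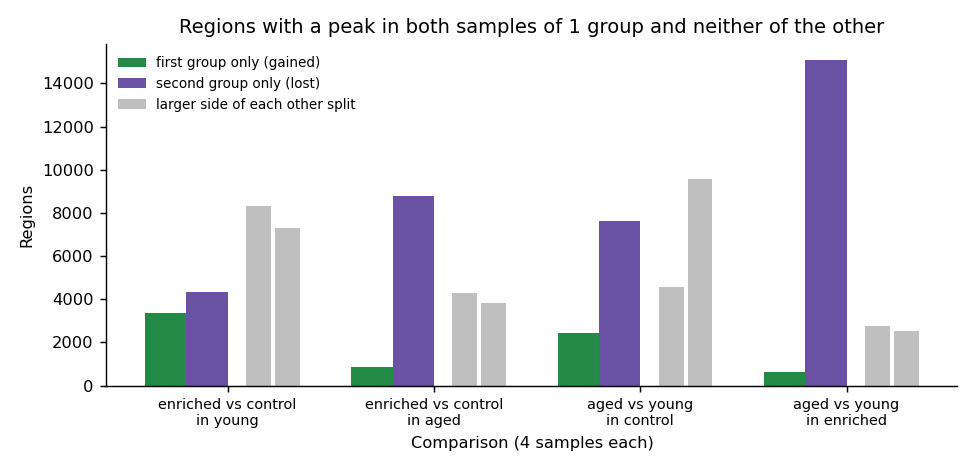
Number of regions with a peak in both samples of 1 group and neither of the other, for 4 comparisons of 2 samples with 2; green bars are regions of the first-named group only, purple bars of the second only, and grey bars the larger side of each other split of the same samples. The purple bars for enriched against control in aged (8778) and aged against young in enriched housing (15072) stand above their grey bars.

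Relative to the length of each list, limma with 1 spread shared by all groups called 1 Mb windows that differed between aged enriched and aged control samples. By limma, 37 windows were higher and 19 lower in aged enriched than in aged control samples, 56 of 1548, with 372 at an unadjusted p under 0.05 where chance gives 77.4. The clearest rise was at 6 to 7 Mb of chromosome 16 (log2 difference 2.71 ± 0.47 SE, limma adjusted p = 0.00246), with 7 and 14 peaks in the enriched and 3 and 1 in the control lists. Neighbouring windows at 91 to 92 Mb (1.69 ± 0.30 SE) and 92 to 93 Mb (1.42 ± 0.25 SE) of chromosome 15 rose too (limma adjusted p = 0.00246 each). Peaks fell at 148 to 149 Mb of chromosome 7 (−1.13 ± 0.22 SE, limma adjusted p = 0.00291), with 14 and 11 peaks in enriched and 58 and 41 in control lists. They also fell at 147 to 148 Mb of chromosome 4 (−0.85 ± 0.19 SE, limma adjusted p = 0.0156) and at 73 to 74 Mb of chromosome 15 (−0.82 ± 0.19 SE, limma adjusted p = 0.0220). Windows that rose held few peaks (median of 14.1 per sample) and windows that fell held many (51.4), against 25.4 over all windows. The median log2 difference over all windows was 0.11, and after quantile normalization, which set it to −0.015, limma called 9 higher and 2 lower. All 56 windows kept their direction after it, with a median change of 0.90 in the called direction against 1.04 before. In equally long lists limma called 44 higher and 67 lower, of which 13 and 13 were among the 56.

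By share of peaks, chromosomes 3 (17.0% more, limma adjusted p = 0.00374), 13 (14.3% more, adjusted p = 0.00374) and 16 (12.9% more, adjusted p = 0.0178) rose and chromosome 4 fell (log2 difference −0.15, adjusted p = 0.0230) in aged enriched samples, each in the limma fit. The number of chromosomes called by limma went from 4 to 2 without aged control replicate 1 and to 13 without aged enriched replicate 1.

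**Figure D5:**
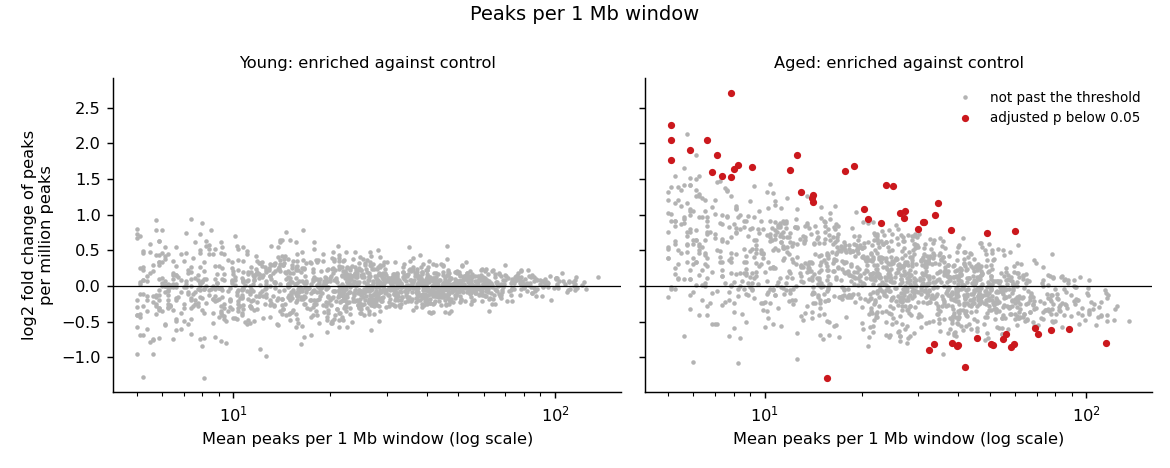
log2 fold change of peaks relative to list length between enriched and control samples (vertical) against mean peaks per 1 Mb window over the 8 samples (horizontal, log scale), for young (left) and aged (right) mice; each point is 1 of 1548 windows and red points have a limma adjusted p below 0.05. There are 0 red points in young mice and 37 above and 19 below zero in aged mice.

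These window calls depended on single samples and on the fit. Without aged control replicate 2 limma called 0 windows, without aged control replicate 1 it called 19 higher and 2 lower, without aged enriched replicate 1 it called 155 and 138, without aged enriched replicate 2 it called 53 and 38, and without any 1 young sample 6 to 11 higher and 1 to 2 lower. A limma fit of the 4 aged samples alone called 0 (216 at an unadjusted p under 0.05), as did windows of 250 kb and a score of at least 100. The calls thus rested on the spread shared with the young samples, which varied less by array weight. A pseudocount in proportion to list length left 13 higher and 8 lower. With flat pseudocounts of 0.25, 1 and 4 peaks limma called 13, 37 and 132 windows higher.

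Over both ages, enriched housing separated few regions and 1 window. All 4 enriched and no control samples had a peak in 22 regions, led by chromosome 16 at 90518730 to 90519890, chromosome 8 at 47585897 to 47586743 and chromosome 11 at 120699455 to 120701297. All 4 control and no enriched samples had a peak in 327 regions, led by chromosome 5 at 36226038 to 36227834, chromosome 2 at 92826053 to 92828151 and chromosome 19 at 6396740 to 6398407. Of the 35 splits of the 8 samples, 10 separated as many regions in total as the 349 of housing. In the limma fit 1 window rose, at 91 to 92 Mb of chromosome 15 (log2 difference 1.07 ± 0.22 SE, adjusted p = 0.0448), which was also among the leading windows in aged mice. It had 32, 25, 13 and 19 peaks in the enriched lists and 12, 35, 10 and 6 in the control lists. By limma 0 windows were higher with a proportional or smaller pseudocount, in equally long lists, after quantile normalization, at 250 kb and with a score of at least 100. The same held without either aged control sample, young control replicate 1 or either young enriched sample. Without aged enriched replicate 1 limma called 56 higher and 74 lower windows, and without aged enriched replicate 2 it called 4 and 13. Chromosome 13 had 8.53% more of the peaks in enriched samples (limma adjusted p = 0.0140), a call that was lost without either aged control sample or any 1 young sample.

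Between ages, regions with peaks in young samples only far outnumbered those with peaks in aged samples only. All 4 young and no aged samples had a peak in 1401 regions. The leading ones lay on chromosome 6 at 144288225 to 144289982 (scores 164 to 348), on chromosome 18 at 65762762 to 65764672 (123 to 320), on chromosome 15 at 27754576 to 27756189 and 36415175 to 36417136, and on chromosome 6 at 97125444 to 97126976. All 4 aged and no young samples had a peak in 15 regions, led by chromosome 4 at 139583607 to 139585381, chromosome 8 at 111443329 to 111444289 and chromosome 19 at 24290243 to 24291200. The split of the 8 samples into the 4 longest and the 4 shortest lists also separated 1416 regions, the total of the split by age. It differs from the split by age only in that young control replicate 1 and aged control replicate 1 change sides. With equally long lists 438 regions were in young and 38 in aged samples only, and each of the other splits then separated at most 296, the highest being again the split by the original list lengths.

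Within control housing 7613 regions had a peak in both young and neither aged sample, led by chromosome 7 at 25199823 to 25202881 and chromosome 9 at 72465106 to 72468153, and 2445 had the reverse, led by chromosome 15 at 78657430 to 78659645 and chromosome 14 at 26692726 to 26694281. The direction turned without aged control replicate 2 (10576 and 21053), when 1 aged sample was enough to count. The total of 10058 lay between the 7000 and 10721 of the other splits of those samples. Within enriched housing 15072 regions had a peak in both young and neither aged sample, against 648 with the reverse, and equally long lists gave 5029 and 1171. Without aged enriched replicate 1 these were 20151 and 14543, and without replicate 2 they were 20266 and 10071. The larger set was led by chromosome 11 at 112923910 to 112929626 (scores 396 to 791 in the young control and 419 to 521 in the young enriched lists, and 207 to 289 in the aged control lists). The smaller set was led by a region near the end of the X chromosome at 166430819 to 166432656, with a peak in all 4 aged samples and in young control replicate 2. The total of 15720 was above the 5140 and 4970 of the other splits.

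For age, limma called 0 windows over both housings, with 149 at an unadjusted p under 0.05. The lowest limma adjusted p was 0.0646, at 37 to 38 Mb of chromosome 19 (log2 difference 0.90 ± 0.19 SE, aged minus young). Next were 69 to 70 Mb of chromosome 14 (1.01 ± 0.24 SE) and 51 to 52 Mb of chromosome 1 (−1.04 ± 0.24 SE), both with a limma adjusted p of 0.0956. Without aged enriched replicate 2 limma called 56 higher and 47 lower windows for age, and without aged enriched replicate 1 it called 6 and 4. No chromosome changed its share of peaks with age by limma (smallest adjusted p 0.0757), and without aged enriched replicate 2 limma called 8.

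In the fit with 1 shared spread, the effect of housing was called different between ages at 1 of 1548 windows. In the limma fit this was 6 to 7 Mb of chromosome 16, where the log2 difference between enriched and control was larger in aged than in young mice by 3.45 ± 0.66 SE (adjusted p = 0.0204). Peak counts there were 11 and 13 in young control, 9 and 5 in young enriched, 3 and 1 in aged control, and 7 and 14 in aged enriched samples. With full lists and all samples, chromosome 3 was the only chromosome whose share of peaks differed in this way (log2 0.26 ± 0.05 SE, limma adjusted p = 0.0248). Both calls were lost without either aged control sample or any 1 young sample, and both with a score of at least 100. The window was also lost with a smaller or proportional pseudocount, in equally long lists and after quantile normalization, and at 250 kb limma called 0 windows higher. Without aged enriched replicate 1 limma called 31 higher and 54 lower windows and 11 chromosomes for this difference, and in equally long lists it called 6 chromosomes.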

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

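Of the tests below, the proportional pseudocount, the 56 windows in equally long lists without the minimum, the split by list length, both tests on the X chromosome and the counts of regions under other splits were chosen after the result was seen. Aged enriched replicate 2 lay far from the other aged samples in its density of peaks on X relative to the autosomes (0.816% against 0.405% to 0.474%). Young control replicate 1 lay far from the other control samples in the same measure (0.745% against 0.467% to 0.474%). These rest on 17 and 22 peaks, 24 combinations of group and measure were examined, and chance gives such a signal in about 5% of groups. The housing effect differed between aged and young mice at 6 to 7 Mb of chromosome 16 (log2 difference 3.45, limma adjusted p = 0.0204) and in the share of peaks on chromosome 3 (0.26, limma adjusted p = 0.0248).

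The first pattern is the 56 windows that differed between aged enriched and aged control samples. Without aged enriched replicate 2 the median change in the called direction was 1.02 on the log2 scale over the 54 windows that met the minimum. These windows gave the same median with all samples, and 54 of 54 kept their sign. The 56 windows were called with aged enriched replicate 1 included, which favours its sign, so this does not exclude replicate 2 alone. In equally long lists 26 of the 56 stayed past the limma threshold. Of the others, 15 fell below the minimum of peaks for the fit. The median change over the 41 that met it was 0.95, against 0.89 for the same windows in full lists, and over all 56 without the minimum it was 1.11. These windows were chosen for their difference, which favours their direction in lists drawn from the same peaks. The cut to 25548 peaks also sets the whole list of aged enriched replicate 1 against only the top-scoring part of longer lists. Equally long lists therefore do not remove what goes with list length and do not decide whether it is the cause. The tables argue against the fixed pseudocount as the whole cause, since 21 of the windows stayed past the limma threshold with a pseudocount in proportion to list length. With a score of at least 100 only 32 of the windows met the minimum, 29 of these kept their sign, 3 turned and 0 stayed past the threshold. Their median change was 0.99, against 0.82 for the same windows in full lists, and the filter left 2535 peaks in aged enriched replicate 1 and 22310 in replicate 2. Without aged control replicate 2 limma called 0 of them, although the median change was 0.97, and the fit of aged samples alone called 0. Aged enriched replicate 2 alone and list length stay open. Housing, read depth and capture efficiency remain open and untested, as 2 samples per group and unknown read numbers do not separate them.

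The second pattern is the 1416 regions that age separated, 1401 of them with peaks in young samples only. List length could account for a large part of it, because the split into the 4 longest and the 4 shortest lists also separated 1416. That split differs from age only by young control replicate 1 and aged control replicate 1, so an effect of age would raise its count too. The 2 splits therefore do not tell length from age. The number of peaks alone does not account for all of it, because in equally long lists age still separated 476 regions, 1.61 times the 296 of the next split. That next split is again the one by original list length, so cutting the lists is not shown to remove what goes with length, such as read depth. Over the 35 splits with full lists, 2 separated as many as age, the highest other being the 1416 by length, and 10 separated at least the 349 of housing, so chance cannot be excluded for either. Age itself, and a lower yield or depth in aged samples, stay open.

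The third pattern is the scarcity of peaks on X. A single copy of X, as in males, would lower reads and scores there. Taking scores to scale with reads, the density on X was at most 4.09% of that predicted from the autosomal peaks with a score of 100 or more, which argues against copy number as the whole cause. Removal or loss of reads on X before peak calling cannot be told apart from low 5hmC, because each list kept at least 5 peaks on X away from its distal end but no read numbers are known. The sex of the mice is not given in the sources used here. No biological explanation was tested, since every group shows the same scarcity.

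A limma fit of 4 samples against 4 called 0 windows for housing and 0 for age, so all 35 of 35 splits called at least as many by construction, and the count says nothing about chance. The highest other split called 12 windows, setting young control replicate 1, both aged control samples and aged enriched replicate 1 against the rest. Whether this is a structure of the samples or the highest of many splits was not tested.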

How the results depend on the processing

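The proportional pseudocount, array weights, peaks set to 1 kb, fits of 1 age alone, overlap with assignments within each age, leaving out samples from overlap, width and the region counts of 2 samples against 2, and the replicate block and permutation within the other factor for width were chosen after the data were seen. Of 243 comparisons of a main value or count with another setting, 77 lost or gained a call or moved by over 1.5-fold. With 1 sample left out 112 of 240 did so. None of the differences in peak number, length, width and overlap among these changed sign. The other comparisons were counts, for which no sign was recorded. The larger set of some pairs of region counts did turn with 1 sample left out, as given below. Among single windows, chromosomes and ratios 33 of 334 changed a call or moved with another setting and 46 of 272 with 1 sample left out. With another setting 1 window changed sign (77 to 78 Mb of chromosome 18 in young mice, −0.030 in equally long lists). With 1 sample left out ratios changed sign in 5 cases. These were peak number with housing in young samples (log2 0.42 without young control replicate 2 and 0.017 without young enriched replicate 1), length in the same comparison (0.37 without young control replicate 2) and peak number with age in control housing (0.12 without young control replicate 2 and 0.012 without aged control replicate 2). In the comparisons of 4 samples with 4, peak number, length and width kept their direction and side of the threshold under every other setting tried. For permutation within the other factor and the replicate block this was fixed in advance. They leave the difference as it is, and their exact permutation p cannot go below 0.0556. Median width reached that floor within the other factor, for housing and for age. Autosomes only, gaps of 500 bp and peaks set to 1 kb ended no call and left counts within 1.5-fold, while the difference in overlap was 2.34 points with peaks set to 1 kb. A setting that alters the peaks, the samples or the rule for presence alters region counts by construction, in either direction. What set the direction, and the cause for window calls and overlap, were not tested. The alternatives per gene, gene list and gene feature were not run, for want of an mm9 annotation. Unknown read depth limits every comparison of list lengths.

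With a score of at least 100, the difference in overlap was 3.43 points, and with assignments within each age it was 1.24 points (exact permutation p = 0.333). Regions of enriched only and control only then numbered 619 and 1268 in young and 199 and 1747 in aged samples, those of aged only and young only 372 and 2219 in control and 149 and 3594 in enriched housing, and over all 8 samples housing separated 7 and 71 and age 2 and 363. In equally long lists these were 1762 and 1781 in young, 3860 (control only) in aged, 2911 (young only) in control housing, 1171 and 5029 in enriched housing, 44 and 145 for housing and 38 and 438 for age. With 50% of the region covered they were 298 (enriched only, aged samples), 251 (aged only, enriched housing), 5 (enriched only), 4 (aged only) and 2136 (young only).

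For aged enriched against aged control, limma called 0 higher and 0 lower windows at 250 kb, with a score of at least 100 and in aged samples alone. It called 8 and 4 with array weights, 180 and 55 with base pairs under peaks, 13 and 8 with a pseudocount of 0.25 peak and with the proportional pseudocount, and 9 and 2 after quantile normalization. It called 83 higher with no minimum, 132 higher with a pseudocount of 4 peaks, and 44 higher and 67 lower in equally long lists. For housing over both ages it called 0 higher at 250 kb, in equally long lists, with the 0.25 and proportional pseudocounts, after quantile normalization and with a score of at least 100, and 4 with array weights, 2 with base pairs and 3 with a pseudocount of 4 peaks. For age it called 2 higher with array weights, a pseudocount of 4 peaks and quantile normalization, and 1 with no minimum. For the interaction it called 0 higher at 250 kb, in equally long lists, with the 0.25 and proportional pseudocounts, after quantile normalization and with a score of at least 100, 2 with base pairs, and 2 lower with array weights. Chromosomes past the limma threshold in equally long lists were 10 for aged housing, 5 for both ages and 6 for the interaction, and with a score of at least 100 they were 2, 0 and 0.

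Leaving out 1 sample moved the log2 difference with age to −1.60 to −0.90 for length and −0.63 to −0.29 for width, and the difference in overlap to 1.66 to 7.05 points. Region counts ranged over 4715 to 16458 (enriched only) and 8214 to 27850 (control only) in young, 1247 to 16851 and 11677 to 37454 in aged, 3283 to 21053 (aged only) and 10576 to 36429 (young only) in control housing, and 1125 to 14543 and 20151 to 36971 in enriched housing. Omitting a sample from a group leaves 1 sample to meet its criterion, and it turned which set of a pair was larger for young and aged housing and for age in control housing. Over all samples they ranged over 33 to 241 and 369 to 1038 for housing and 20 to 169 and 1697 to 3481 for age. Windows called by limma ranged over 0 to 155 higher and 0 to 138 lower for aged housing, 0 to 56 and 0 to 74 for both ages, 0 to 56 and 0 to 47 for age, and 0 to 31 and 0 to 54 for the interaction. Chromosomes called ranged over 2 to 13 for aged housing, 0 to 6 for both ages, 0 to 8 for age and 0 to 11 for the interaction. A lone sample was assumed to vary like the other groups.

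Samples with the same replicate number did not deviate together (correlations of −0.14 to 0.10 over 6 pairs of groups, across windows), so the number does not pair them. With a replicate block limma called 46 higher and 27 lower windows for aged housing, 1 higher window for age and 0 chromosomes for the interaction, and the block changed no other call.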

Other observations

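The highest-scoring peak on the X chromosome lay in a cluster at its distal end, from 166424378 to 166436369 (mm9), in every sample except young control replicate 1 and young enriched replicate 1. The cluster is near the pseudoautosomal region that pairs with the Y chromosome and was singled out after its values were seen. In the aged control lists its best peak ranked 17 of 59260 and 9 of 38000 by score, with scores of 790 and 593. In the aged enriched lists it ranked 753 of 25548 and 2556 of 30832, with scores of 136.26 and 186.49. In the young lists it ranked 7824 of 43709, 12787 of 78980, 40403 of 57492 and 6747 of 59462, with scores of 60.2 to 137. Every aged sample thus ranked it above every young sample. By score the order did not hold, as aged enriched replicate 1 lay below young control replicate 2 (137.4) and young enriched replicate 2 (136.31). No test on this cluster is given, because the cluster was chosen after these values were seen, and ranks from lists of different lengths do not measure a change in level. The cluster held 4, 4, 2 and 4 peaks in aged and 2, 3, 1 and 2 in young samples (difference of means 1.5), and the length under its peaks was 4742 ± 3183 bp in aged and 3234 ± 1646 bp in young samples (SD, n = 4 each). Sequence at this chromosome end is repetitive, and the number of its copies in these mice was not analysed here.

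The balance between peak-dense and peak-sparse windows lay outside the range of the young samples in most aged samples. Against the mean of the young samples, the slope of the log2 difference on log2 density over 1548 windows was 0.13 and 0.12 in the aged control samples, −0.03 and −0.18 in the aged enriched samples and −0.05 to 0.01 in the young samples, each compared with the other young ones. In the sparsest 10% of windows the median log2 difference was −0.22 and −0.20 in aged control and 0.36 and 0.48 in aged enriched samples, against 0.01 to 0.15 in young samples. In equally long lists the slopes were 0.10 and −0.01 in aged control, −0.19 and −0.34 in aged enriched and −0.11 to 0.03 in young samples, and in the sparsest 10% the median was 0.004 and 0.18, 0.52 and 0.64, and 0.10 to 0.31 in the same order. Both aged enriched samples then lay outside the young range in both measures, and aged control replicate 2 lay within it. In the 56 windows that differed between aged enriched and aged control samples, the aged enriched mean departed from the young mean in the called direction in 56, and the aged control mean in 2. The median log2 difference from the young mean, taken in the called direction, was 0.46 for aged enriched and −0.67 for aged control samples. The calls thus reflect departures of both aged groups from the young samples, in opposite directions. These windows were chosen by the difference itself, so this does not test whether housing moved aged mice toward young ones.

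Chromosome 18 held neighbouring regions that differed in their pattern, an observation also made after the values were seen. The region at 65782866 to 65785412 had a peak in all 6 samples outside the aged enriched group, and the one at 65762762 to 65764672 had a peak in all 4 young and no aged samples.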
